A study of Mus musculus with 3 samples.

How the data were processed

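The series measured RNA and chromatin accessibility in the same nuclei with a droplet assay (10x Genomics Multiome). Nuclei came from 3 pools, each holding females of 1 treatment and males of another. Per the file headers, the deposited matrices were written by cellranger-arc 2.0.2 and hold raw whole-number counts for every barcode, UMI counts for 32285 genes and counts for the peaks called in each pool. Per the submitters' processing notes, Cell Ranger 8.0.1, Seurat 5 and the build mm39 were used, with no role given for each. The gene positions in the deposited files matched GENCODE release 21 on GRCm38, where 32158 genes were found by identifier and 28406 (88.3%) had a start within 1000 bp, so positions are given on GRCm38. The aligner settings are not given in the sources used here.

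The pools held 723926, 725546 and 719603 barcodes and 94020589, 149514123 and 97264470 gene UMIs. Barcodes with at least 1000 UMIs, 500 genes and at most 5% mitochondrial UMIs were kept, leaving 6243, 12638 and 7619. The UMI minimum had been written as a rule on the density of UMIs between 500 and 5000, but in pool 2 that rule gave 4558 and parted glia from neurons, so 1000 was used in all pools after seeing the data, and the written rule is among the alternatives. Scrublet in scanpy, with an expected rate of 0.06, marked 154 (2.47%), 1387 (10.97%) and 614 (8.06%) barcodes as doublets, which were removed. A nucleus was female with at least 2 UMIs of Xist and at least 4 times the Y-linked UMIs (Uty, Kdm5d, Ddx3y, Eif2s3y), and male with Y-linked UMIs of at least 2 times Xist plus 1. Nuclei with both (76, 205 and 124) or neither (711, 942 and 593) were left out. The latter were shallow, with median UMIs of 2105, 1856.5 and 2147, and over 5000 UMIs 96.1%, 96.4% and 95.8% of nuclei were assigned. These genes assigned the nuclei, so their levels are no results and no independent check of the labels.

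Counts were scaled to 10000 UMIs per nucleus, and 3000 variable genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1.5 gave the clusters. A cluster was named from markers fixed before the data were examined, with a score of at least 1.0 and at least 3 markers detected in 10% of nuclei, and names are written X-like. Other clusters stayed unnamed, 4.75% to 9.53% of a profile. Listed genes other than markers were kept out of the clustering, and genes that lead a cluster are left out as results. Vtn, which leads a vascular cell-like cluster, is named in precursor-like nuclei beside the vascular marker sums. Free RNA was read from barcodes of at most 50 UMIs.

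The counts of each class were summed per sex and treatment, giving 6 profiles, 2 per treatment, with at least 20 nuclei each (50 in subclasses). The main test was edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr, robust) with treatment and sex, 2 residual degrees of freedom, all profiles sharing 1 estimate of the spread and Benjamini-Hochberg adjustment over the genes tested, at 0.05. The 3 comparisons were 5-MeO-DMT against vehicle, TBG against vehicle and 5-MeO-DMT against TBG. Pool could replace sex with 1 residual degree of freedom, and both together left none, so that such values have no test. A difference of effects between classes was tested as an interaction over 12 profiles, with each set of nuclei as block. Values per profile are in CPM, computed here from the counts.

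The 16 gene lists fixed before the data were examined were immediate early, delayed activity-regulated, MAPK feedback, glucocorticoid-induced, heat shock and chaperone, unfolded protein response, cold-induced RNA-binding protein, circadian clock, serotonin receptor and transporter, glutamate receptor, postsynaptic scaffold, mTOR and translation control, neurotrophin signalling, cholesterol synthesis, dissociation and nuclear stress, and cytosolic carry-over genes. They were tested with limma 3.58.1 (camera, preset correlation 0.01, and again with the estimated correlation), adjusted over the lists per class and comparison, where at least 5 members were tested. Lists overlap, Dusp1 and Per1 for example each standing in 3. Named genes were chosen by a rule fixed in advance. It takes the 8 called genes with the largest change in each direction in excitatory and inhibitory neuron-like nuclei and 3 in other classes, with a mean of at least 10 CPM and the same sign in both sexes. It adds the 5 lowest p-values where under 5 were called, every tested immediate early gene in excitatory neuron-like nuclei and called list members. Predicted gene models (4, 0 and 5 calls in excitatory, 3, 1 and 5 in inhibitory neuron-like and 24, 4 and 20 in astrocyte-like nuclei, in the order of comparisons above) were counted and not named. Some genes that the rule selects are not reported here.

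For shares of nuclei with an Arc UMI each nucleus was thinned to 2000 UMIs and shallower ones were left out, and intervals are exact binomial (95%). Chromatin was counted over regions present in all pools (81224 of 135535) and tested like genes, with windows of 10 kb around gene starts and of 2 and 50 kb as alternatives. For a rule on sex that also used chromatin, Y-linked peaks were limited to 2000 bp around the starts of the 4 Y-linked genes.

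The tests were run first on simulated counts with 200 changed genes. Changed genes had a mean of at least 10 CPM. Counts varied around a single mean per gene by the trend of spread with expression, with no gene-specific spread and no difference between pools. Recovery in the real data can therefore be lower. For 5-MeO-DMT against vehicle, 100% of genes changed 2-fold and 87% changed 1.5-fold were called in excitatory neuron-like nuclei, with 13 calls on unchanged genes of 17864, 82% and 46% in inhibitory neuron-like (9 of 13403) and 43% and 15% in astrocyte-like nuclei (2 of 10749). In L4/5 IT-like nuclei it was 81% and 23% (2 of 14165), and for the interaction of inhibitory and excitatory neuron-like nuclei 72% and 26% (8 of 13294). Of 200 chromatin regions changed 2-fold, 54% were called in excitatory neuron-like nuclei (6 calls on unchanged regions) and 13% in astrocyte-like nuclei (3). Alternatives covered scaling, DESeq2 1.42.0, the filter, terms for sex and pool, depth, doublets, the sex rule, the UMI minimum and each profile left out. Correlations between the compounds were set beside 20 simulations of unchanged groups. Software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.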

Results

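The series held 3 pools of nuclei from the medial prefrontal cortex of 8-week-old C57BL/6J mice, a standard inbred laboratory strain, taken 1 hour after an intraperitoneal injection of 5-MeO-DMT, TBG or vehicle. 5-MeO-DMT is a hallucinogenic tryptamine that activates serotonin receptors, and TBG is a name used for tabernanthalog, a compound made as an analog of ibogaine. The labels give no dose for either compound. Each pool mixed females of 1 treatment with males of another, so the sex of a nucleus gave its treatment: female vehicle with male TBG (pool 1), female TBG with male 5-MeO-DMT (pool 2) and female 5-MeO-DMT with male vehicle (pool 3). The title of the series names neuronal plasticity induced by compounds in the absence of immediate early gene activation, and the comparisons here ask which genes differed between the 3 treatments in each type of nucleus. The labels do not say how many animals stood behind each sex and treatment or that they were processed apart. Every p-value of a single gene or region therefore measures the spread between these 6 profiles, 2 per treatment, which may be partly technical. A limma camera p-value instead compares listed genes or regions with the others and depends on the correlation assumed between them. However small, it is no test over replicate animals.

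The pools held 94020589, 149514123 and 97264470 gene UMIs (unique molecular identifiers, which count RNA molecules). After filtering there were 1846 female vehicle, 2962 male vehicle, 8389 female TBG, 3485 male TBG, 3411 female 5-MeO-DMT and 1854 male 5-MeO-DMT nuclei. The female nuclei of pools 1, 2 and 3 carried on average 16.4, 14.1 and 15.2 UMIs of Xist against 0.102, 0.048 and 0.06 UMIs of Uty, Kdm5d, Ddx3y and Eif2s3y together. The male nuclei carried 0.039, 0.065 and 0.032 of Xist against 5.09, 3.92 and 4.33. These means follow from the rule that assigned the nuclei and do not test it. Chromatin counts near the starts of the Y-linked genes were not used by that rule. In pools 1, 2 and 3 they were present in 14.8%, 5.1% and 12.9% of male and 0.3%, 0.1% and 0.2% of female nuclei. Most male nuclei thus had no such count, and their assignment rests on RNA alone. Counts were summed per profile and class. Excitatory neuron-like sums came to 15212868 (female vehicle), 23244133 (male vehicle), 61966152 (female TBG), 31185028 (male TBG), 26113697 (female 5-MeO-DMT) and 12935329 UMIs (male 5-MeO-DMT). Inhibitory neuron-like sums ranged from 1604766 to 7976442 UMIs and astrocyte-like sums from 609883 to 2831282. Excitatory neuron-like nuclei made up 54.2% to 62.5% of a profile, inhibitory neuron-like 10.1% to 11.9%, astrocyte-like 9.42% to 11.4%, oligodendrocyte-like 2.28% to 3.37%, oligodendrocyte precursor-like 1.56% to 3.09%, microglia-like 1.25% to 2.75% and vascular cell-like 2.91% to 8.02%. These shares also depend on the dissection, the sort of nuclei and the sex rule, and were not tested.

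**Figure D1:**
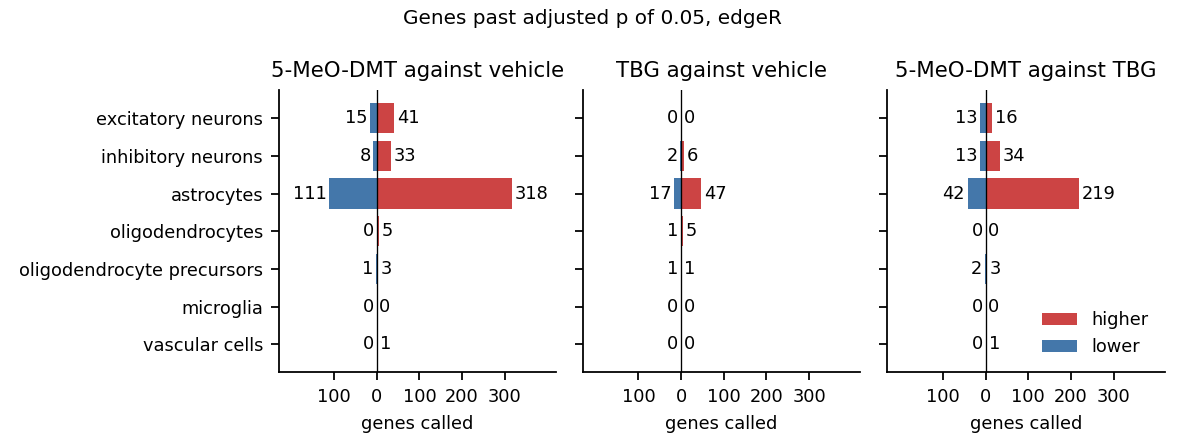
Number of genes past an adjusted p of 0.05 (edgeR, x axis) in each class of nuclei (y axis) for the 3 comparisons, higher to the right and lower to the left. Astrocyte-like nuclei had 429 calls for 5-MeO-DMT against vehicle, 64 for TBG against vehicle and 261 for 5-MeO-DMT against TBG, against 56, 0 and 29 in excitatory neuron-like nuclei.

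In excitatory neuron-like nuclei, 5-MeO-DMT raised 41 and lowered 15 of 17864 tested genes against vehicle (edgeR, 2 profiles per treatment). Fkbp5, a co-chaperone induced by glucocorticoids (ENSMUSG00000024222, chromosome 17), rose from 49.1 ± 1.23 to 116 ± 4.22 CPM (counts scaled to the total of the profile; mean ± SD, n = 2), a log2 change of 1.24 (SE 0.103, edgeR adjusted p = 0.00196). Hes1, a transcriptional repressor of the Notch pathway, rose by 1.40 and B4galt1, a galactosyltransferase, by 1.46, each at an edgeR adjusted p of 0.00196. Further raised genes included Tiparp (1.46), an activity-induced ADP-ribosyltransferase, the retinoic acid receptor Rara (0.99), the growth factor Fgf5 (0.96) and the neurotrophin gene Bdnf (0.65, edgeR adjusted p = 0.0316). Among the lowered genes were Grm3, which encodes a metabotropic glutamate receptor (-0.54), the junction gene Jcad (-0.82), the integrin Itgb8 (-0.81) and the calcium-binding protein gene Calb1 (-0.77). The kinase gene Hunk (-0.71), Dact2 (-0.69), the transcription factor Etv1 (-0.67), Tmem196 (-0.66) and Wls (-0.65), a carrier of Wnt proteins, also fell. Calb1 and Etv1 are also markers of layers, and both were called again within a layer, Calb1 in L2/3 IT-like and Etv1 in L5 IT-like nuclei. Their number rested on single profiles. Without the female vehicle, male TBG, female TBG, male 5-MeO-DMT, female 5-MeO-DMT or male vehicle profile it was 344, 4, 4, 232, 576 and 261, with the remaining profile of that treatment assumed to vary like the others, and with pool in place of sex as a term it was 981.

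The 33 immediate early genes tested had log2 changes above 0 with 5-MeO-DMT in excitatory neuron-like nuclei in 33 of 33 cases, with a median of 0.84. The list stood above other genes (limma camera, adjusted p = 7.12e-24 with the preset correlation, adjusted p = 0.594 with an estimated correlation). Over all genes 2 members passed. They were the nuclear receptor gene Nr4a3 (1.32, 95% interval 0.90 to 1.73, edgeR adjusted p = 0.0316) and the AP-1 subunit gene Jun (1.10, 0.74 to 1.46, edgeR adjusted p = 0.0305). Adjusted over the list alone, 11 passed. Common activity markers spread widely between profiles. Arc, whose protein acts at synapses, had 29.3 ± 24.4 CPM with vehicle and 56.9 ± 24.2 with 5-MeO-DMT (mean ± SD, n = 2). Its log2 change was 1.00 with a 95% interval of -2.42 to 4.41. For the transcription factor genes Fos, Npas4 and Egr1 the changes were 0.84 (-2.02 to 3.71), 0.53 (-1.41 to 2.47) and 0.23 (-2.80 to 3.25), so that a change was not detectable. The other members came to 3.37 (Atf3), 2.05 (Ccn1), 1.79 (Nr4a2), 1.67 (Fosb), 1.59 (Egr2), 1.45 (Fosl2), 1.21 (Gadd45b), 1.16 (Csrnp1), 1.07 (Fosl1), 1.07 (Egr4), 0.90 (Amigo3), 0.87 (Klf4) and 0.87 (Dusp1). Smaller values were 0.81 (Sik1), 0.78 (Btg2), 0.71 (Maff), 0.69 (Gadd45g), 0.66 (Junb), 0.57 (Klf10), 0.53 (Egr3), 0.47 (Arl4d), 0.42 (Ier2), 0.39 (Klf2), 0.33 (Ier5), 0.21 (Nr4a1), 0.19 (Trib1) and 0.005 (Ier3). Of these, Atf3, Ccn1, Nr4a2, Fosb, Egr2, Fosl2, Gadd45b, Csrnp1 and Gadd45g passed over the list alone. The list median was 0.51 without the female vehicle and 1.57 without the male vehicle profile, and 0.81 with pool and sex terms, which compare treatments within pools.

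With TBG the same list had a median of 0.22 against vehicle, with 26 of 33 members above 0 (limma camera, adjusted p = 0.0208, adjusted p = 0.851 with an estimated correlation). By edgeR 0 members were called over all genes and 0 adjusted over the list alone. The log2 changes were 0.22 for Arc (95% interval -3.10 to 3.53), -0.21 for Fos (-3.03 to 2.61), 0.01 for Npas4 (-1.87 to 1.90) and 0.05 for Nr4a3 (-0.37 to 0.46). For the rest they were 0.82 (Csrnp1), 0.66 (Atf3), 0.59 (Sik1), 0.58 (Maff), 0.53 (Fosb), 0.45 (Fosl1), 0.43 (Gadd45g), 0.38 (Btg2), 0.36 (Gadd45b), 0.36 (Amigo3), 0.34 (Nr4a2), 0.34 (Jun), 0.33 (Dusp1), 0.32 (Egr2) and 0.31 (Klf10). Lower in order came 0.27 (Klf2), 0.20 (Klf4), 0.18 (Egr4), 0.17 (Trib1), 0.15 (Ccn1), 0.11 (Junb), 0.08 (Nr4a1), 0.006 (Ier2), -0.006 (Ier3), -0.03 (Ier5), -0.05 (Egr3), -0.18 (Arl4d), -0.36 (Fosl2) and -0.38 (Egr1). The direction of this median depended on the vehicle profile used. It was -0.25 without the female vehicle, 0.96 without the male vehicle, 0.41 without the male TBG, 0.06 without the female TBG profile and 0.56 with pool and sex terms. Fos was called lower (-1.17) and Npas4 lower (-0.71) without the female vehicle, and both were called higher without the male vehicle (1.53 for Fos and 1.07 for Npas4). Between the compounds, the list was higher with 5-MeO-DMT in 33 of 33 members, with a median difference of 0.58 (limma camera, adjusted p = 4.03e-12, adjusted p = 0.392 with an estimated correlation). That difference was 0.18 without the female and 0.90 without the male 5-MeO-DMT profile, and 0.24 with pool and sex terms. Only Nr4a3 was called between the compounds over all genes (1.27, 0.88 to 1.65, edgeR adjusted p = 0.0399), and 8 members passed adjusted over the list alone. The differences for Arc (0.78, -2.37 to 3.93), Fos (1.05, -1.57 to 3.67) and Npas4 (0.52, -1.29 to 2.32) had intervals that include 0.

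**Figure D2:**
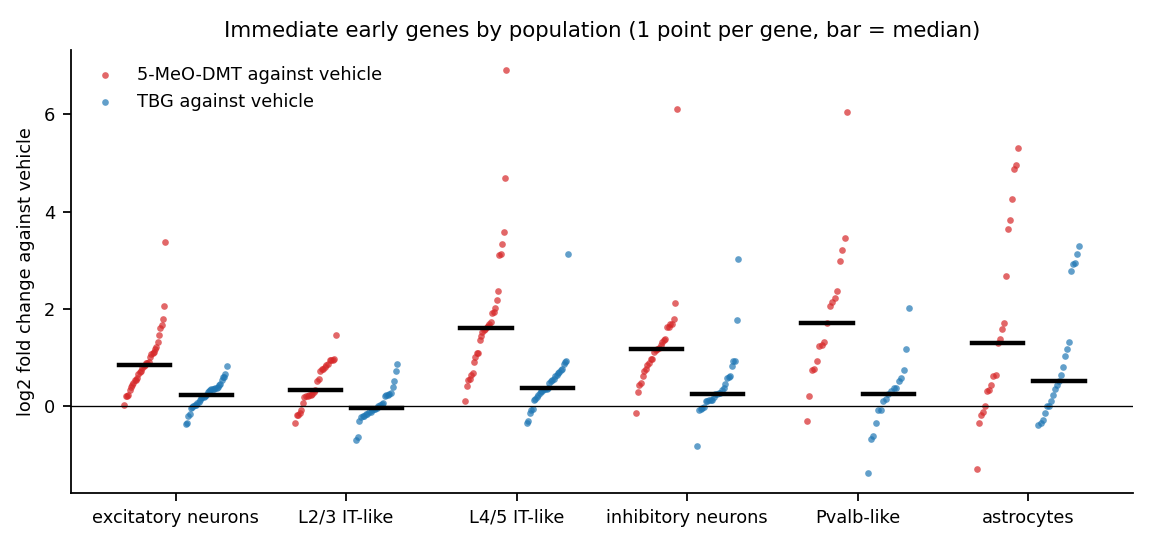
Log2 fold change against vehicle (y axis) of each tested immediate early gene (1 point per gene) in 6 populations of nuclei (x axis), 5-MeO-DMT in red and TBG in blue, with the median as a bar. The 5-MeO-DMT medians were 0.84 in excitatory neuron-like, 0.32 in L2/3 IT-like, 1.60 in L4/5 IT-like, 1.16 in inhibitory neuron-like, 1.70 in Pvalb-like and 1.29 in astrocyte-like nuclei.

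Other lists also moved with 5-MeO-DMT in excitatory neuron-like nuclei. Of 27 delayed activity-regulated genes, 2 rose (Bdnf and Tiparp) and 14 were higher and 1 lower adjusted over the list alone, with a median of 0.31 (limma camera, adjusted p = 1.03e-12, adjusted p = 0.594 with an estimated correlation). The 19 glucocorticoid-induced genes had a median of 0.27 and 1 call, Fkbp5 (adjusted p = 1.68e-05, adjusted p = 0.594 with an estimated correlation), and 3 were higher and 1 lower adjusted over the list alone. The 13 genes of the dissociation and nuclear stress list, which overlaps the immediate early genes, had a median of 0.42, with 1 call (Jun) and 2 adjusted over the list alone (adjusted p = 1.83e-05, adjusted p = 0.594 with an estimated correlation). Without the female vehicle, female 5-MeO-DMT or male vehicle profile the delayed median was 0.16, 0.18 and 0.48 and the dissociation median -0.08, 0.09 and 0.95, and without the male 5-MeO-DMT profile the latter was 0.86. The limma camera test did not pass for MAPK feedback (median 0.25, limma adjusted p = 0.0795), neurotrophin signalling (0.03, 0.0795), heat shock and chaperone (0.02, 0.626), unfolded protein response (0.05, 0.0941), cold-induced RNA-binding protein (-0.01, 0.865) or circadian clock genes (0.06, 0.0941). Nor did it for serotonin receptor and transporter (0.05, 0.629), glutamate receptor (-0.04, 0.626), postsynaptic scaffold (0.02, 0.309), mTOR and translation control (-0.03, 0.9), cholesterol synthesis (0.00, 0.663) or cytosolic carry-over genes (0.05, 0.629).

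TBG against vehicle gave 0 calls in excitatory neuron-like nuclei by edgeR, with 2290 genes at an unadjusted p under 0.05 and 71 calls by DESeq2. The 5 lowest p-values belonged to B4galt1 (0.93), the GTPase gene Rhou (0.78), Epm2a, which encodes the glycogen phosphatase laforin (0.64), Fgf5 (0.96) and the adhesion gene Nectin3 (-0.58), each at an edgeR adjusted p of 0.0571. The unfolded protein response genes had a median of -0.18 with 2 of 19 above 0 (limma camera, adjusted p = 0.000701). The medians were -0.13 for cholesterol synthesis genes (0.0059), -0.22 for cold-induced genes (0.0208) and 0.17 for MAPK feedback genes (0.0208). For each of these 4 lists limma camera gave adjusted p = 0.713 with an estimated correlation, and 2, 2, 2 and 1 of their members passed adjusted over the list alone, with 0 over all genes. Without the female vehicle, male TBG, female TBG or male vehicle profile the unfolded protein response median was -0.30, -0.09, -0.25 and -0.05 and the MAPK feedback median 0.09, 0.28, 0.10 and 0.34. The unfolded protein response and cholesterol synthesis tests no longer passed without the male TBG or male vehicle profile (cholesterol medians -0.09 and -0.08), the cold-induced test without the female TBG or male vehicle profile (-0.20 and -0.31) and the MAPK feedback test without the female vehicle or female TBG profile. The count was unstable: in the same order of left-out profiles as above it was 643, 0, 0, 652, 810 and 168, and it was 897 with the pool term.

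Between the compounds, 16 genes were higher and 13 lower with 5-MeO-DMT than with TBG in excitatory neuron-like nuclei. Those higher included Bdnf (0.80, 95% interval 0.59 to 1.02, edgeR adjusted p = 0.0215), the chromatin gene Baz1a (1.55), the potassium channel gene Kcnk13 (0.80) and Hist3h2a (0.80). Prrt1 (0.73), which encodes an auxiliary protein of AMPA receptors, the Nogo receptor homolog Rtn4rl1 (0.65) and the kinase gene Sik2 (0.62) were higher too. Those lower were led by Trmt9b (-1.03), Oacyl (-0.97), Dach1 (-0.88), Epm2a (-0.76), Ranbp17 (-0.69), Zkscan16 (-0.66), Camk1g (-0.66) and the MAPK-responsive factor Etv5 (-0.59, edgeR adjusted p = 0.0362). The compounds could not be told apart at Fgf5 (difference 0.00, -0.27 to 0.27, edgeR adjusted p = 1), while Fkbp5 differed by 0.55 (0.33 to 0.77) without passing (0.0663). Delayed activity-regulated genes were higher with 5-MeO-DMT in 24 of 27 cases (median 0.23, 2 called, 6 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 4.93e-10). The same held for unfolded protein response genes in 17 of 19 cases (median 0.25, 0 called, 9 adjusted over the list alone, 2.46e-08) and cholesterol synthesis genes in 16 of 16 (median 0.12, 0 called, 1 adjusted over the list alone, 0.000507). All 3 had adjusted p = 0.392 with an estimated correlation (limma camera). The delayed median was 0.11 without the female 5-MeO-DMT profile, the unfolded protein response median 0.16 without the male TBG profile and the cholesterol median 0.21, 0.19 and 0.19 without the female TBG, male 5-MeO-DMT or female 5-MeO-DMT profile. Left-out profiles in the same order gave 786, 0, 0, 677, 228 and 904 calls, and the pool term 1436.

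In inhibitory neuron-like nuclei, 5-MeO-DMT raised 33 and lowered 8 of 13403 genes. Immediate early genes led. Fos rose from 5.15 ± 5.02 to 24.9 ± 1.46 CPM (mean ± SD, n = 2), a log2 change of 2.11 (95% interval 1.32 to 2.89, edgeR adjusted p = 0.0109). Fosb (6.12, from 0.266 CPM), Dusp1 (1.63), a phosphatase that acts on MAP kinases, Junb (1.38), Npas4 (1.68), Nr4a3 (1.78) and Fosl2 (1.62) also rose. With these 7 called and 16 adjusted over the list alone, the 26 tested members had a median of 1.16 (limma camera, adjusted p = 1.19e-36, adjusted p = 0.0764 with an estimated correlation). The synaptic scaffold gene Homer1 (0.69, edgeR adjusted p = 0.000356) and Tiparp (0.96) rose among the delayed genes. Fkbp5 (1.32, edgeR adjusted p = 6.17e-08) and Zbtb16 (0.53) rose among the 16 glucocorticoid-induced genes. That list had 3 calls with Dusp1, 5 adjusted over the list alone and a median of 0.39 (limma camera, adjusted p = 1.2e-09, adjusted p = 0.197 with an estimated correlation), or 0.22 without the male 5-MeO-DMT and 0.24 without the male vehicle profile. Other raised genes were the phosphodiesterase gene Pde3a (1.55), Lonrf3 (1.54), Trim67 (1.48) and Cenpa (1.34). Lowered genes were St8sia4 (-0.72), the insulin-degrading enzyme Ide (-0.70) and Col25a1 (-0.62) among others. DESeq2 called 5 genes, and without the 6 profiles in the order above edgeR called 58, 59, 54, 46, 67 and 114.

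TBG raised 6 and lowered 2 genes against vehicle in inhibitory neuron-like nuclei. Raised were Pde3a (1.48), Fkbp5 (0.85, edgeR adjusted p = 0.00166), Lypd6 (0.73), which modulates nicotinic receptors, Zfp941 (0.71) and the nuclear export receptor Xpo1 (0.63), and lowered were the glucocorticoid receptor gene Nr3c1 (-0.67) and the adhesion gene Flrt2 (-0.50). The immediate early genes had a median of 0.25, with 21 of 26 above 0 and 0 adjusted over the list alone (limma camera, adjusted p = 0.00268, adjusted p = 0.402 with an estimated correlation). That median was 0.23 without the female vehicle, 0.43 without the male TBG and 0.16 without the female TBG profile, and the list no longer passed in the first and last case. Fos changed by 0.44 (95% interval -0.40 to 1.28), Arc by 0.10 (-0.62 to 0.81) and Npas4 by -0.05 (-0.81 to 0.72), none of them called. Between the compounds, 34 genes were higher and 13 lower with 5-MeO-DMT. Higher were Fos (1.67, 1.05 to 2.28), Npas4 (1.73, 1.13 to 2.32), Nr4a3 (1.66), Fosb (3.10), Fosl2 (1.39), Dusp1 (1.37), Junb (1.01), Egr1 (0.84) and Homer1 (0.53). The same held for the noncoding gene Mir670hg (1.06, edgeR adjusted p = 4.72e-07), the stem cell factor gene Kitl (0.87), Ier5l (0.77) and the heat shock genes Hspa1a (2.55) and Hsph1 (0.78). Lower were Cwc22 (-0.71), Mtmr2 (-0.69), Stat3 (-0.68), Glra2 (-0.67), Calb1 (-0.61), Ranbp17 (-0.55) and Slc44a5 (-0.49). The immediate early list differed by a median of 0.75 (8 called, 11 adjusted over the list alone, limma camera adjusted p = 6.67e-28, adjusted p = 0.101 with an estimated correlation). DESeq2 called 0 genes for TBG and 1 between the compounds. Without the profiles in the same order, edgeR called 96, 23, 0, 34, 34 and 56 for TBG and 166, 9, 24, 75, 15 and 167 between the compounds.

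In astrocyte-like nuclei (clusters 3, 12 and 25) 318 genes were raised and 111 lowered by 5-MeO-DMT of 10749 tested. This count of 429 was the largest of any class with the sex term, but with pool in place of sex it was 419 against 981 in excitatory neuron-like nuclei. Without the female vehicle, female 5-MeO-DMT or male vehicle profile excitatory neuron-like nuclei had more calls as well. Cluster 12 held most astrocyte-like nuclei in both 5-MeO-DMT profiles and cluster 3 most in the vehicle and TBG profiles. With vehicle, cluster 12 held 3 of 200 female and 7 of 279 male nuclei. With TBG it held 177 of 893 and 100 of 335, and with 5-MeO-DMT 288 of 389 and 142 of 181. No fit was made within these clusters, so a change in their mix and a change within them cannot be told apart. Of 21 immediate early genes, 10 were called higher: Nr4a3 (5.31), Fosl2 (4.96), the kinase gene Sik1 (4.87, edgeR adjusted p = 1.87e-07), Arl4d (4.25), Klf4 (3.83), Nr4a2 (3.64), Ccn1 (2.67), Junb (1.59), Nr4a1 (1.38) and Dusp1 (1.29). Several started near 0, Sik1 going from 1.81 ± 1.18 to 52.9 ± 9.39 CPM (mean ± SD, n = 2). The list had a median of 1.29 and, adjusted over the list alone, 11 higher and 1 lower (limma camera, adjusted p = 7.17e-17, adjusted p = 0.139 with an estimated correlation). Fos itself did not pass (1.71, 95% interval 0.68 to 2.73, edgeR adjusted p = 0.051). Cholesterol synthesis genes rose in 10 of 16 cases, among them Fdps (0.91), Idi1 (0.91), Hmgcs1 (0.83) and Cyp51 (0.79). Insig1 (0.74), Fdft1 (0.74), Nsdhl (0.67) and Msmo1 (0.51) rose as well. The list had a median of 0.76 and 12 adjusted over the list alone (limma camera, adjusted p = 7.89e-12, adjusted p = 0.215 with an estimated correlation). Unfolded protein response genes rose in 6 of 17 cases, with the chaperone genes Hyou1 (1.68), Pdia3 (0.99), Dnajc3 (0.81) and Hspa5 (0.64), the transcription factor Xbp1 (1.10) and Herpud1 (0.93). They had a median of 0.64 and 12 adjusted over the list alone (limma camera, adjusted p = 9.61e-10, adjusted p = 0.205 with an estimated correlation). Of 18 glucocorticoid-induced genes 8 rose, Fkbp5 by 1.44, Errfi1 by 1.28, the kinase Pdk4 by 1.17, Zbtb16 by 1.12 and Tsc22d3 by 0.78 among them. With 9 adjusted over the list alone, the median was 0.82 (limma camera, adjusted p = 2.45e-10, adjusted p = 0.323 with an estimated correlation), or 0.26 without the female 5-MeO-DMT and 1.25 without the male vehicle profile. Delayed activity-regulated genes rose in 8 of 21 cases, including Rgs2 (1.71), Cdkn1a (1.71), the clock gene Per1 (1.36), Crem (1.20), the BDNF receptor gene Ntrk2 (1.03, edgeR adjusted p = 1.62e-08), Dclk1 (0.84), Mbnl2 (0.70) and Tiparp (0.54). Of these genes 9 passed adjusted over the list alone, with a median of 0.46 (limma camera, adjusted p = 1.83e-10, adjusted p = 0.139 with an estimated correlation), or 0.70 without the female 5-MeO-DMT and 0.74 without the male vehicle profile. Bag3 (1.29), Ciart (1.06) and Sesn1 (0.61) were further raised list members. The largest falls were AI849053 (-2.11), Thnsl1 (-2.09) and the Notch target Hes5 (-2.03, edgeR adjusted p = 4.24e-06), and the MAPK-responsive Etv4 fell by 0.81. DESeq2 called 160 genes, and without the profiles in the order above edgeR called 65, 374, 385, 385, 365 and 82.

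TBG raised 47 and lowered 17 genes in astrocyte-like nuclei. Arl4d (3.29, edgeR adjusted p = 0.000152) and Sik1 (2.94) were the called immediate early genes among 21, and 6 passed adjusted over the list alone. The list median was 0.51 (limma camera, adjusted p = 3.76e-07, adjusted p = 0.402 with an estimated correlation), or 1.01 without the male vehicle profile and 0.85 with pool and sex terms. The kinase gene Dapk2 rose by 2.20, and Hes5 (-2.16, edgeR adjusted p = 1.59e-06), Ankrd26 (-1.43) and Trib2 (-1.06) fell. Delayed genes had a median of 0.22 with 0 called and 4 adjusted over the list alone (limma camera, adjusted p = 0.000585, adjusted p = 0.402 with an estimated correlation). Glucocorticoid-induced genes had 0.29, 0 and 5 (adjusted p = 5.85e-07, adjusted p = 0.563 with an estimated correlation). Both tests failed without the female vehicle profile, at medians of 0.27 and 0.14, and without the male vehicle profile the medians were 0.35 and 0.59, without the male TBG profile 0.36 for the delayed genes and without the female TBG profile 0.52 for the glucocorticoid-induced genes. Cholesterol synthesis genes had a median of -0.01 (limma camera, adjusted p = 0.849). Cytosolic carry-over genes, a sign of RNA from outside the nucleus, had a median of 0.19 with TBG (limma camera, adjusted p = 8.24e-05, adjusted p = 0.669 with an estimated correlation), or 0.38 without the male and 0.01 without the female TBG profile. Between the compounds, 219 genes were higher and 42 lower with 5-MeO-DMT. Higher were Hist1h4d (2.42), Nr4a2 (2.33), Nr4a3 (2.20, 95% interval 1.33 to 3.06), Sik1 (1.93), Ccn1 (1.5), Nr4a1 (1.39), Crem (1.32), Zbtb16 (0.80), Ntrk2 (0.69, 0.50 to 0.89) and Tsc22d3 (0.52). Lower were Mamdc2 (-1.80), Dtx1 (-1.28), Gap43 (-1.05) and Shc3 (-0.63). Cholesterol synthesis genes were higher with 5-MeO-DMT (median 0.72, 10 of 16 called, 11 adjusted over the list alone, limma camera adjusted p = 1.08e-19, adjusted p = 0.206 with an estimated correlation), with Mvd (1.60), Lss (1.36) and Fdps (1.05) in front. So were the unfolded protein response genes (median 0.59, 6 called, 11 adjusted over the list alone, 5.01e-12, adjusted p = 0.186 with an estimated correlation), with Pdia4 (1.35) and Xbp1 (1.28). The fall of Hes5 did not differ detectably between the compounds (0.12, -0.48 to 0.73, edgeR adjusted p = 0.946), nor did the rise of Fkbp5 (0.62, 0.21 to 1.03, 0.154). Without the profiles in the same order the counts were 0, 34, 30, 145, 153 and 0 for TBG and 59, 128, 88, 301, 167 and 79 between the compounds.

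**Figure D3:**
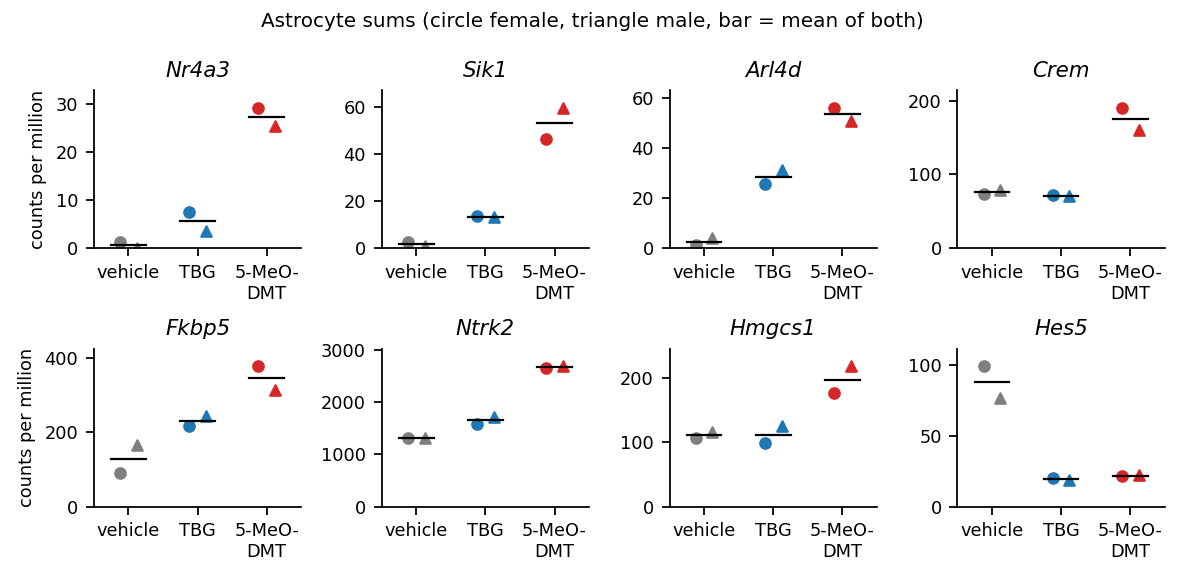
CPM (y axis, from 0) of 8 genes in the astrocyte-like sums of each profile by treatment (x axis), with the female profile as a circle, the male profile as a triangle and their mean as a bar. Sik1 and Arl4d lie between the vehicle and 5-MeO-DMT levels with TBG, while Crem and Hmgcs1 lie near the vehicle level and Hes5 near the 5-MeO-DMT level.

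The remaining classes had few nuclei and few calls. In oligodendrocyte precursor-like nuclei (29 to 181 per profile) 5-MeO-DMT raised 3 genes, the phosphodiesterase genes Pde10a (1.42, edgeR adjusted p = 3.67e-06) and Pde3a (1.22) and Fkbp5 (1.25). It lowered 1, Vtn, a gene of vascular cells. The vascular markers in these nuclei summed to 227 and 157 CPM with vehicle against 17.0 and 0 with 5-MeO-DMT. TBG raised the NMDA receptor gene Grin2a (2.59) and lowered Prrx1 (-1.65), and between the compounds Pde3a (1.11), Pde10a (0.85) and Nkain3 (0.75) were higher and Grin2b (-2.0) and Syt1 (-1.20) lower with 5-MeO-DMT. Grin2a, Grin2b and Syt1 are genes of neurons, and excitatory neuron markers in these nuclei summed to 278 CPM in the female TBG and 163 in the male TBG profile, against 139 and 152 with vehicle and 132 and 114 with 5-MeO-DMT. Inhibitory neuron markers there did not follow TBG, at 348.3 and 348.3 CPM with vehicle, 325.5 and 365.3 with TBG and 280.4 and 387.2 with 5-MeO-DMT. Oligodendrocyte-like nuclei (42 to 225) had 5 genes raised by 5-MeO-DMT, such as Frmpd4 (3.05), Tma16 (2.53) and Elmsan1 (1.76), and 5 raised and 1 lowered by TBG, such as Frmpd4 (3.67), Mgat4c (2.64) and Fbxo32 (-2.27). Frmpd4 and Mgat4c are genes of neurons, and inhibitory neuron markers in these nuclei summed to 304 and 288 CPM with vehicle, 373 and 376 with TBG and 466 and 369 with 5-MeO-DMT. Excitatory neuron markers there showed no such order, at 321.4 and 197.7 CPM with vehicle, 264.2 and 232.0 with TBG and 182.7 and 524.5 with 5-MeO-DMT. Vascular markers came to 8.7 and 8.2, 84.4 and 72.2, and 7.2 and 41.0 CPM. Vascular cell-like nuclei (clusters 17, 19, 22 and 26, in unequal shares) had 1 call with 5-MeO-DMT, the chemokine gene Ccl2 (6.80 against vehicle, edgeR adjusted p = 0.00364, and 3.99 against TBG, 0.00742). The immediate early genes had a median of 1.38 (20 of 20 above 0, 0 called, 8 adjusted over the list alone, limma camera adjusted p = 2.73e-14, adjusted p = 0.313 with an estimated correlation). In that class edgeR called 0 genes for TBG, with 209 at an unadjusted p under 0.05 and 0 by DESeq2. Microglia-like nuclei (32 to 162) gave 0 calls by edgeR in all 3 comparisons, with 164, 88 and 61 genes at an unadjusted p under 0.05 and 1, 1 and 0 calls by DESeq2. The lowest p-values were at Tmtc2 (-2.87), Abcc3 (3.17) and Ldb2 (-2.81) with 5-MeO-DMT, each at an edgeR adjusted p of 0.631. Oligodendrocyte-like nuclei gave 0 between the compounds by edgeR, with 159 at an unadjusted p under 0.05 and 0 by DESeq2. Single profiles moved these counts too. For 5-MeO-DMT against vehicle in the order above, oligodendrocyte-like nuclei gave 0, 20, 18, 4, 100 and 0 calls, precursor-like 0, 3, 3, 5, 1 and 2, microglia-like 64, 12, 22, 3, 1 and 280 and vascular cell-like 3, 116, 116, 271, 220 and 20. For TBG against vehicle the same leave-outs gave 3, 39, 5, 30, 29 and 0, then 1, 3, 1, 7, 8 and 1, then 64, 2, 6, 0, 0 and 175, then 0, 12, 0, 16, 0 and 0 calls. Between the compounds they gave 0, 2, 8, 22, 21 and 0, then 1, 7, 0, 11, 0 and 1, then 24, 0, 14, 1, 0 and 13, then 17, 22, 52, 320, 103 and 17.

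Within the excitatory neuron-like nuclei, layer and projection types differed in their calls. L4/5 IT-like nuclei (intratelencephalic neurons of layers 4 and 5, clusters 2 and 7) had 188 genes raised and 26 lowered by 5-MeO-DMT. With TBG 0 were called by edgeR, with 1346 at an unadjusted p under 0.05 and 0 by DESeq2, and between the compounds 149 were higher and 17 lower with 5-MeO-DMT. Raised genes included Nr4a3 (3.33, SE 0.2, edgeR adjusted p = 6.18e-06), Fosl2 (3.13), the hyaluronan-binding Tnfaip6 (5.68) and Sik2 (1.82). Bdnf (1.70), Tiparp (2.32), the prohormone convertase Pcsk1 (1.59), Scg2 (1.79), Nptx2 (1.69) and Homer1 (1.18) rose too, and the 30 immediate early genes had a median of 1.60 with 12 called. With TBG the median there was 0.36, but 0.70 with pool and sex terms, where 5-MeO-DMT had 1.57 and the difference fell from 1.24 to 0.79. With TBG Nr4a3 changed by 0.54 (edgeR adjusted p = 0.48) and Fosl2 by 0.30 (0.78). Tnfaip6 (4.56), Nr4a3 (2.79) and Bdnf (1.66) were higher with 5-MeO-DMT than with TBG. L2/3 IT-like nuclei had 46, 30 and 91 calls in the 3 comparisons, with Fkbp5 raised by 5-MeO-DMT (1.36) and by TBG (0.79, edgeR adjusted p = 0.0319), and an immediate early median of 0.32 with 5-MeO-DMT and -0.05 with TBG. With pool and sex terms these were 0.32 and 0.61, and the difference between the compounds went from 0.44 to -0.06, so that the order of the compounds in this layer is open. With pool in place of sex L4/5 IT-like nuclei had 748, 153 and 525 calls and L2/3 IT-like nuclei 125, 0 and 67 by edgeR (for the 0, 1497 at an unadjusted p under 0.05 and 4 by DESeq2), and the rise of Fkbp5 with TBG was no longer called. Pvalb-like nuclei, a type of inhibitory neuron, had 30, 3 and 44 calls and medians of 1.70 and 0.24. L5 IT-like nuclei had 99, 12 and 13 calls (73 of the 99 lower), L6 CT-like 59, 24 and 36, L5 ET-like 8, 1 and 10, L5/6 NP-like 5, 4 and 4 and L6 IT-like 4, 10 and 5. Left-out profiles in the order above gave 482, 183, 103, 122, 113 and 469 calls for 5-MeO-DMT in L4/5 IT-like nuclei, 615, 0, 0, 0, 0 and 25 for TBG and 831, 45, 20, 203, 37 and 832 between the compounds. In L2/3 IT-like nuclei they gave 86, 7, 3, 97, 143 and 58, then 157, 0, 0, 244, 217 and 5, then 335, 0, 0, 405, 44 and 328. In Pvalb-like nuclei they gave 34, 39, 40, 20, 25 and 72, then 42, 14, 13, 26, 28 and 30, then 108, 7, 33, 31, 31 and 117. DESeq2 called 0 genes in Pvalb-like nuclei in each comparison. In L4/5 IT-like nuclei cluster 7 held most of the female 5-MeO-DMT and male vehicle profiles and cluster 2 most of the others.

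The difference of treatment effects between inhibitory and excitatory neuron-like nuclei was tested directly. With 5-MeO-DMT 13 genes changed more upward and 6 more downward in inhibitory neuron-like nuclei. Fosb (difference 4.83), Pde3a (2.76), Hunk (0.98) and Mir670hg (0.96, edgeR adjusted p = 6.37e-05) lay above, and Tnfaip6 (-4.58), St8sia4 (-1.11) and Col25a1 (-0.87, edgeR adjusted p = 1.46e-05) below. These are examples chosen after their values were seen. The rise of Fkbp5 did not differ detectably (0.05, SE 0.15, edgeR adjusted p = 0.991). The immediate early list lay 0.27 higher in inhibitory neuron-like nuclei (limma camera p = 0.00233, p = 0.424 with an estimated correlation).

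**Figure D4:**
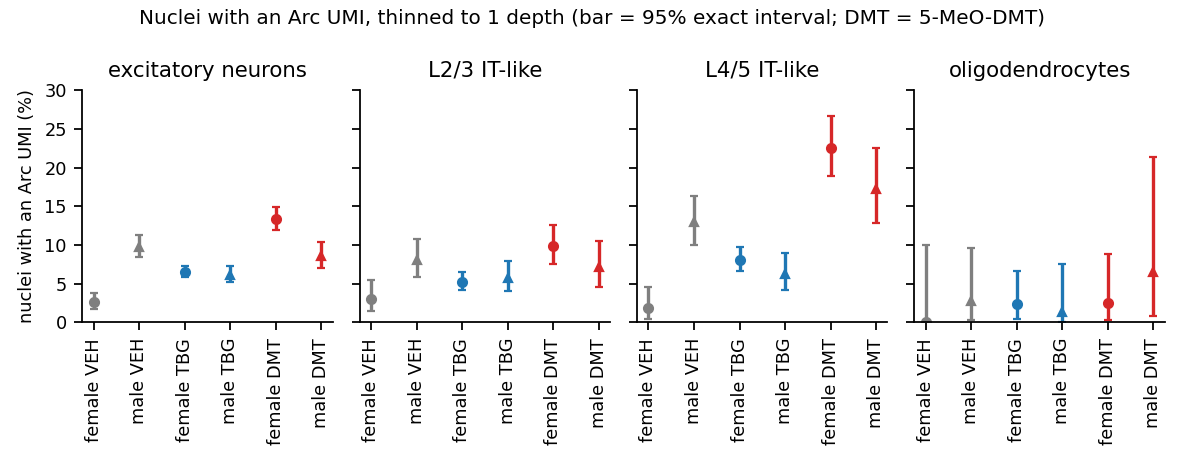
Percent of nuclei with at least 1 Arc UMI after thinning each nucleus to 2000 UMIs (y axis) in each of the 6 profiles (x axis; VEH is vehicle and DMT is 5-MeO-DMT) for 4 populations, with 95% exact binomial intervals as bars. The vehicle profiles of excitatory neuron-like nuclei lie at 2.60% and 9.79%, on both sides of the TBG profiles at 6.51% and 6.18%.

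Arc was read again as the share of nuclei with a UMI, each nucleus thinned to 2000 UMIs. Among excitatory neuron-like nuclei it was 2.60% in the female and 9.79% in the male vehicle profile, 6.51% and 6.18% with TBG and 13.3% and 8.57% with 5-MeO-DMT. The exact 95% binomial intervals, which cover counting error only, were 1.7% to 3.78%, 8.47% to 11.2%, 5.85% to 7.23%, 5.17% to 7.33%, 11.9% to 14.9% and 7.01% to 10.3%. Unthinned, at median depths of 10708 to 14728 UMIs, the shares were 15.8%, 37.4%, 28.8%, 33.0%, 46.2% and 29.7% in the same order. Oligodendrocyte-like nuclei, which should lack Arc and had 2523 to 2768 UMIs, gave 0%, 2.74%, 2.34%, 1.39%, 2.53% and 6.45% from 31 to 128 nuclei. In L4/5 IT-like nuclei the shares were 1.83%, 12.9%, 8.09%, 6.28%, 22.6% and 17.3%. With 2 profiles against 2 an exact permutation test cannot go below p = 0.333, so no test was made. The vehicle profiles differed from one another by more than TBG differed from either.

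Chromatin accessibility was counted in the same excitatory neuron-like nuclei over 81153 regions. 5-MeO-DMT raised 307 and lowered 149 regions, TBG raised 89 and lowered 18, and 0 differed between the compounds by edgeR (4093 at an unadjusted p under 0.05, with no other tool run on regions). In simulated counts 54% of regions changed 2-fold by 5-MeO-DMT against vehicle were called, so differences can be missed. The 93 regions within 10 kb of the starts of immediate early genes had a median log2 change of -0.067 with 5-MeO-DMT (34 above 0, 1 called lower, limma camera p = 0.0317, p = 0.543 with an estimated correlation) and of -0.056 with TBG (p = 0.2). The regions with the lowest p-values, chosen after their values were seen, lay nearest Anks3 (chromosome 16, 4975929 to 4976873, 12197 bp from its start, 1.16) and Ppp1r9b (chromosome 11, 94997863 to 94998746, 1.32), which encodes spinophilin. Another lay nearest the MAP kinase phosphatase gene Dusp5 (chromosome 19, 53507176 to 53508115, 1.07, edgeR adjusted p = 0.000259). The region nearest Anks3 was also called with TBG (0.87, edgeR adjusted p = 0.00793), against the same vehicle profiles. Regions were not refitted with a profile left out or with a pool term. Positions are on GRCm38.

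The 2 compounds were finally compared over all genes. The log2 changes against vehicle correlated across genes with r = 0.472 in excitatory neuron-like, 0.56 in inhibitory neuron-like and 0.628 in astrocyte-like nuclei. Both comparisons share the vehicle profiles, and 20 simulations of unchanged groups gave mean correlations of 0.566, 0.583 and 0.581. The covariances were 0.0466, 0.0635 and 0.115 against simulated values of 0.0377, 0.0543 and 0.0743. The simulated counts had no gene-specific spread and no difference between pools, and both can raise the covariance. The excess over the simulated values therefore cannot be read as a shared effect of the compounds. With a different vehicle profile for each compound the correlations were -0.144 and 0.11, -0.09 and 0.035, and 0.099 and 0.155. In astrocyte-like nuclei 41 genes were raised by both and 9 lowered by both, against 1.39 and 0.176 for independent lists, and part of this excess may come from the shared vehicle profiles.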

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

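The differences between astrocyte-like and excitatory neuron-like nuclei and between L4/5 IT-like and L2/3 IT-like nuclei, the depth ratio and pool term for the astrocyte-like counts and the pool term for the vehicle profiles were tests chosen after the result was seen. Treatment effects differed between classes by edgeR interaction tests. Between inhibitory and excitatory neuron-like nuclei 19 genes differed for 5-MeO-DMT against vehicle, 13 for TBG against vehicle and 16 for 5-MeO-DMT against TBG. Between astrocyte-like and excitatory neuron-like nuclei the counts were 300, 62 and 160.

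With the sex term, astrocyte-like nuclei had more genes called with 5-MeO-DMT (429) than excitatory neuron-like nuclei (56), but this order turned with pool in place of sex (419 against 981) and without the female vehicle (65 against 344), female 5-MeO-DMT (365 against 576) or male vehicle profile (82 against 261). Greater depth is argued against, since the astrocyte sums held at most 0.0527 of the UMIs of the excitatory sums in any profile, as their fewer and shallower nuclei imply. The counts alone do not rank the responses, since the fits pooled the spread between genes to different degrees. The median prior degrees of freedom were 25.1 in astrocyte-like and 7.8 in excitatory neuron-like nuclei. In the same order, 1395 of 10749 and 1739 of 17864 genes had an unadjusted edgeR p under 0.05 with 5-MeO-DMT. With TBG the numbers were 873 and 2290, at 64 and 0 calls. Free RNA from excitatory neurons, if equal in amount between profiles, would have to change at least as much at its source. The genes raised in astrocyte-like nuclei had a median log2 change of 0.07 (quartiles -0.05 and 0.23) in excitatory neuron-like nuclei against 0.99 in astrocyte-like nuclei. Free RNA in unequal amounts is not covered by this comparison. Excitatory neuron markers in astrocyte-like nuclei summed to 151.4 and 181.5 CPM with vehicle, 197.1 and 201.7 with TBG and 154.6 and 224.6 with 5-MeO-DMT. A difference between pools and a treatment response that differs in size between the classes cannot be told apart, because 1 residual degree of freedom remains with pool and single profiles turn the order too. Free RNA in unequal amounts, other sources of RNA and the number of animals stay open.

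Between L4/5 IT-like and L2/3 IT-like nuclei 107 genes differed for 5-MeO-DMT against vehicle and 103 for 5-MeO-DMT against TBG, with Btg2 (2.37 higher in L4/5 IT-like nuclei) and Scg2 (1.59) as examples chosen after their values were seen. For TBG against vehicle 0 differed (edgeR, 803 at an unadjusted p under 0.05, no other tool run), and the immediate early list lay 0.39 higher in L4/5 IT-like nuclei (27 of 31, limma camera p = 9.06e-05, p = 0.194 with an estimated correlation). For the other comparisons the list differed by a median of 1.14 (30 of 31 higher, limma camera p = 2.44e-33, p = 0.0412 with an estimated correlation) and 0.80 (p = 3.98e-33, p = 0.0184 with an estimated correlation). A mixture of clusters 2 and 7 could shift the value, but the lower of the list's medians within them was 1.10, and over the 27 members tested in both subclasses, fitted apart, the median difference was 0.89 and with pool and sex terms 0.98 (quartiles 0.64 and 1.56), which argues against both as the whole source. A layer-dependent response may explain the difference, as a hypothesis.

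The vehicle profiles differed in excitatory immediate early genes, with a median of 0.95 higher in the male profile and 29 of 33 members higher. With treatment and sex held, pool 3 lay 0.86 (quartiles 0.48 and 1.20) above pool 1 and males 0.21 above females, with no residual degrees of freedom. Pool and the vehicle difference cannot be told apart, because each pool holds a single vehicle profile at most and the same fit uses all 6 profiles. A difference in handling, sex or animals could each be the source.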

How the results depend on the processing

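All alternatives were planned except the written UMI rule, clusters 2 and 7 fitted apart, the alternatives in L2/3 IT-like, L4/5 IT-like and Pvalb-like nuclei and those of astrocyte chromatin, which were tests chosen after the result was seen. No paired analysis by replicate number was possible because the groups share fewer than 2 replicate numbers. Each pool did hold 2 treatments, which the main test with the sex term does not use. Tests within pools rest on the pool term fitted in place of sex, with 1 residual degree of freedom. Values with both pool and sex terms have no test. With 2 profiles per treatment neither the counts of called genes nor the correlations between the compounds were stable, and of 9 correlations under another setting 1 stayed, 6 moved and 2 reversed. Both reversals came from the setting in which a difference between pools 1 and 3 enters the 2 effects with opposite signs. Of 246 counts under another setting of the whole set 123 stayed within 1.5 times and 123 moved, and of 180 counts with a profile left out 43 stayed. Named genes were judged by another rule, so their numbers are not comparable with those of the counts. A gene called in neither fit stayed if its direction did, and fits without a test were judged by size and direction. Of 2644 values under another setting 2130 stayed, 400 lost the call, 81 gained it and 0 reversed. With a profile left out it was 919, 491, 111 and 2 of 1548. Of 1722 list medians, judged by the same rule as genes, 1460 stayed, 73 lost the call, 31 gained it, 155 moved and 3 reversed, and with a profile left out 657, 41, 51, 101 and 14 of 864. Of the genes called in excitatory neuron-like nuclei with 5-MeO-DMT, 12 to 56 of 56 were called again under another setting of the whole set and 4 to 56 with a profile left out, and of those in astrocyte-like nuclei 159 to 426 and 62 to 377 of 429. The median log2 change of all genes lay between -0.034 and 0.015 with the main scaling and between -0.042 and 0.012 with size factors of DESeq2. The profiles with fewest nuclei limit depth, and alternatives that left under 20 nuclei in a profile were not run, namely the higher UMI minimum in microglia-like and vascular cell-like nuclei, the stricter sex rule in precursor-like and microglia-like nuclei, the written UMI rule in classes other than excitatory and inhibitory neuron-like nuclei and sex from chromatin in classes other than excitatory neuron-like nuclei. For the values that follow, the cause was not tested, and counts are in the order 5-MeO-DMT against vehicle, TBG against vehicle, 5-MeO-DMT against TBG.

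The counts of classes where at least 1 count moved by over 1.5 times were as follows. With DESeq2 the counts were 144, 71 and 81 (excitatory), 5, 0 and 1 (inhibitory), 160, 21 and 77 (astrocyte), 1, 0 and 0 (oligodendrocyte), 1, 0 and 0 (precursor), 1, 1 and 0 (microglia), 11, 0 and 4 (vascular), 30, 4 and 28 (L2/3 IT), 99, 0 and 72 (L4/5 IT), 0, 0 and 0 (Pvalb). With size factors of DESeq2 in edgeR they were 4, 4 and 7 (precursor), 31, 12 and 47 (Pvalb). Without the filter on low counts they were 425, 435 and 552 (excitatory), 63, 25 and 81 (inhibitory), 462, 100 and 304 (astrocyte), 6, 15 and 0 (oligodendrocyte), 3, 3 and 0 (precursor), 19, 4 and 0 (microglia), 107, 0 and 79 (vascular), 279, 260 and 491 (L2/3 IT), 572, 289 and 583 (L4/5 IT), 34, 25 and 41 (Pvalb). Without the sex term they were 229, 211 and 307 (excitatory), 34, 13 and 45 (inhibitory), 3, 4 and 0 (oligodendrocyte), 5, 4 and 7 (precursor), 43, 0 and 36 (vascular), 114, 50 and 180 (L2/3 IT), 364, 1 and 307 (L4/5 IT), 24, 1 and 35 (Pvalb). With pool in place of sex they were 981, 897 and 1436 (excitatory), 50, 20 and 40 (inhibitory), 14, 4 and 10 (oligodendrocyte), 5, 1 and 3 (precursor), 10, 1 and 5 (microglia), 99, 3 and 59 (vascular), 125, 0 and 67 (L2/3 IT), 748, 153 and 525 (L4/5 IT), 23, 21 and 43 (Pvalb). With sums thinned to the smallest profile they were 20, 2 and 4 (inhibitory), 325, 32 and 147 (astrocyte), 1, 0 and 0 (oligodendrocyte), 0, 0 and 0 (precursor), 12, 0 and 1 (vascular), 68, 19 and 55 (L2/3 IT), 172, 0 and 83 (L4/5 IT), 3, 0 and 0 (Pvalb). With doublets kept they were 12, 0 and 0 (excitatory), 24, 6 and 15 (inhibitory), 2, 4 and 0 (oligodendrocyte), 3, 2 and 0 (precursor). With 2 times the UMI minimum they were 44, 13 and 52 (inhibitory), 1, 4 and 0 (oligodendrocyte). With a stricter sex rule they were 19, 2 and 20 (inhibitory), 1, 0 and 0 (oligodendrocyte), 35, 0 and 26 (vascular). With sex from chromatin and RNA they were 47, 3 and 91 (excitatory).

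In L4/5 IT-like nuclei the counts were 338, 2 and 331 with cluster 2 alone and 29, 1 and 14 with cluster 7 alone. The TBG median of the immediate early list was 0.02 with cluster 7 alone, and 0.55 there with pool and sex terms.

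With doublets kept the shares of nuclei moved. For excitatory nuclei they were 59.96% (male vehicle), 58.41% (female TBG), 59.09% (male 5-MeO-DMT). For astrocyte nuclei they were 9.67% (female TBG). For microglia nuclei they were 1.96% (male vehicle), 2.56% (female TBG), 2.53% (male 5-MeO-DMT).

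With the stricter sex rule the shares moved. For excitatory nuclei they were 67.99% (male vehicle), 61.74% (female TBG), 62.38% (male TBG), 67.86% (male 5-MeO-DMT). For astrocyte nuclei they were 7.65% (male vehicle), 8.56% (male TBG). For oligodendrocyte nuclei they were 1.96% (male vehicle), 2.32% (female TBG), 1.70% (male TBG), 1.80% (male 5-MeO-DMT). For precursor nuclei they were 1.84% (male TBG). For microglia nuclei they were 0.63% (male vehicle), 2.08% (male TBG), 0.93% (male 5-MeO-DMT). For vascular nuclei they were 2.47% (male vehicle), 3.56% (female TBG), 4.71% (male TBG), 1.65% (male 5-MeO-DMT).

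With 2 times the UMI minimum the shares moved. For excitatory nuclei they were 58.10% (female vehicle), 65.73% (male vehicle), 65.40% (female TBG), 60.24% (male TBG), 63.98% (female 5-MeO-DMT), 66.59% (male 5-MeO-DMT). For inhibitory nuclei they were 12.74% (female TBG). For oligodendrocyte nuclei they were 2.60% (male vehicle), 1.65% (female TBG), 2.47% (female 5-MeO-DMT), 1.80% (male 5-MeO-DMT). For microglia nuclei they were 1.04% (female vehicle), 0.57% (male vehicle), 0.70% (female TBG), 1.64% (male TBG), 0.78% (female 5-MeO-DMT), 0.99% (male 5-MeO-DMT). For vascular nuclei they were 5.28% (female vehicle), 1.81% (male vehicle), 1.60% (female TBG), 4.24% (male TBG), 2.72% (female 5-MeO-DMT), 1.05% (male 5-MeO-DMT).

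With an estimated correlation in limma camera the medians of the immediate early list stayed and its adjusted p-values were higher, 0.84 (adjusted p = 0.594), 0.22 (adjusted p = 0.851) and 0.58 (adjusted p = 0.392) in excitatory nuclei, 1.16 (adjusted p = 0.0764), 0.25 (adjusted p = 0.402) and 0.75 (adjusted p = 0.101) in inhibitory nuclei, 1.29 (adjusted p = 0.139), 0.51 (adjusted p = 0.402) and 0.65 (adjusted p = 0.186) in astrocyte nuclei.

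With pool and sex terms, which leave no test, the median of the list was 0.56 in excitatory neurons, TBG against vehicle, 0.24 in excitatory neurons, 5-MeO-DMT against TBG, 0.85 in astrocytes, TBG against vehicle. With pool in place of sex, list medians that changed direction were -0.10 (cytosolic carry-over genes in excitatory neurons, 5-MeO-DMT against vehicle, adjusted p = 0.000821 by limma camera), 0.04 (circadian clock genes in excitatory neurons, TBG against vehicle, adjusted p = 0.0277 by limma camera), -0.08 (MAPK feedback genes in excitatory neurons, 5-MeO-DMT against TBG, adjusted p = 0.0181 by limma camera). With doublets kept the median log2 change of immediate early genes in inhibitory neurons, TBG against vehicle was 0.16 (adjusted p = 0.0759 by limma camera).

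The shares of excitatory neuron-like nuclei with Arc were without thinning 15.78% (female vehicle), 37.41% (male vehicle), 28.79% (female TBG), 32.98% (male TBG), 46.21% (female 5-MeO-DMT), 29.69% (male 5-MeO-DMT), and with 2 or more Arc UMIs required 0% (female vehicle), 0.65% (male vehicle), 0.57% (female TBG), 0.6% (male TBG), 1.96% (female 5-MeO-DMT), 0.96% (male 5-MeO-DMT).

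The correlation of the effects of 5-MeO-DMT and TBG was with called genes only 0.883 (excitatory), 0.853 (inhibitory), with female vehicle for 5-MeO-DMT and male vehicle for TBG -0.144 (excitatory), -0.09 (inhibitory), 0.099 (astrocyte), with male vehicle for 5-MeO-DMT and female vehicle for TBG 0.11 (excitatory), 0.035 (inhibitory), 0.155 (astrocyte). The values over called genes have no simulated counterpart, and the choice of genes and the shared vehicle profiles can raise them. The values with separate vehicle profiles also carry differences between pools, as described above.

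For chromatin the medians of regions near immediate early genes were -0.039 (50 kb window, 5-MeO-DMT against vehicle), 0.107 (astrocytes in place of excitatory neurons, 5-MeO-DMT against vehicle), -0.067 (estimated correlation between regions, 5-MeO-DMT against vehicle), 0.045 (astrocytes in place of excitatory neurons, 5-MeO-DMT against TBG).

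With 1 profile left out in turn the lowest and highest counts were 4 to 576, 0 to 810 and 0 to 904 (excitatory), 46 to 114, 0 to 96 and 9 to 167 (inhibitory), 65 to 385, 0 to 153 and 59 to 301 (astrocyte), 0 to 100, 0 to 39 and 0 to 22 (oligodendrocyte), 0 to 5, 1 to 8 and 0 to 11 (precursor), 1 to 280, 0 to 175 and 0 to 24 (microglia), 3 to 271, 0 to 16 and 17 to 320 (vascular), 3 to 143, 0 to 244 and 0 to 405 (L2/3 IT), 103 to 482, 0 to 615 and 20 to 832 (L4/5 IT), 20 to 72, 13 to 42 and 7 to 117 (Pvalb).

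Log2 values (medians for lists) that reversed with 1 profile left out ranged as follows. The immediate early list in inhibitory neurons with TBG, which lost its call without reversing, stands beside them. Other values that lost or gained a call without reversing are not listed here and are in the counts given above. For 5-MeO-DMT against vehicle, -0.08 (without female vehicle) to 0.95 (without male vehicle) for dissociation and nuclear stress genes in excitatory neurons. For TBG against vehicle, -1.17 (without female vehicle) to 1.53 (without male vehicle) for Fos in excitatory neurons, -0.71 (without female vehicle) to 1.07 (without male vehicle) for Npas4 in excitatory neurons. For the same comparison, -0.25 (without female vehicle) to 0.96 (without male vehicle) for immediate early genes in excitatory neurons, -0.16 (without female vehicle) to 0.23 (without male vehicle) for delayed activity-regulated genes in excitatory neurons. For the same comparison, -0.04 (without female vehicle) to 0.11 (without male vehicle) for circadian clock genes in excitatory neurons, -0.34 (without female vehicle) to 0.31 (without male vehicle) for dissociation and nuclear stress genes in excitatory neurons. For the same comparison, -0.27 (without female TBG) to 0.19 (without male TBG) for cytosolic carry-over genes in excitatory neurons, 0.16 (without female TBG) to 0.43 (without male TBG) for immediate early genes in inhibitory neurons. For the same comparison, -0.37 (without female TBG) to 0.06 (without male vehicle) for unfolded protein response genes in inhibitory neurons, -0.06 (without male TBG) to 0.21 (without female TBG) for circadian clock genes in inhibitory neurons. For the same comparison, -0.14 (without female TBG) to 0.30 (without male TBG) for cytosolic carry-over genes in inhibitory neurons, -0.20 (without female TBG) to 0.09 (without male TBG) for postsynaptic scaffold genes in astrocytes. For 5-MeO-DMT against TBG, -0.14 (without male TBG) to 0.31 (without female TBG) for cytosolic carry-over genes in excitatory neurons, -0.22 (without male TBG) to 0.23 (without female TBG) for cytosolic carry-over genes in inhibitory neurons. For the same comparison, -0.07 (without female 5-MeO-DMT) to 0.59 (without male 5-MeO-DMT) for glucocorticoid-induced genes in astrocytes.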

Other observations

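The tests of the astrocyte genes named here, of astrocyte chromatin, of the score across sexes and of the glucocorticoid list without activity genes were chosen after the result was seen. In astrocyte-like nuclei (clusters 3, 12 and 25), some genes outside the lists changed with both compounds, and these are named after their values were seen. Usp53 rose by 2.36 on the log2 scale with 5-MeO-DMT (95% interval 2.13 to 2.59, edgeR adjusted p = 1.41e-14) and by 1.17 with TBG (0.95 to 1.40, edgeR adjusted p = 3.8e-07), and the difference was 1.18 (0.97 to 1.39). Eprs, which encodes a tRNA synthetase, rose by 2.87 and 1.07 (difference 1.81, 1.51 to 2.10). The phosphodiesterase gene Pde4d (1.72 and 0.53), the deacetylase gene Hdac4 (1.40 and 0.51) and the histone demethylase gene Kdm5b (1.61 and 0.93) had values of the same order. The glucocorticoid receptor gene Nr3c1 fell by 0.63 with 5-MeO-DMT (edgeR adjusted p = 0.0109) and by 0.92 with TBG (edgeR adjusted p = 0.000424).

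Accessibility in astrocyte-like nuclei, over 31993 regions, rose at 171 and fell at 3 with 5-MeO-DMT and rose at 37 and fell at 0 with TBG (edgeR, 2187 and 1430 at an unadjusted p under 0.05), with 0 between the compounds (1162, no other tool run). In simulated counts 13% of regions changed 2-fold by 5-MeO-DMT against vehicle were called, so the 0 does not exclude differences. Peak counts ranged from 392520 (male 5-MeO-DMT) to 2268621 (female TBG). The 491 regions near the 318 raised genes had a median of 0.167 with 5-MeO-DMT (limma camera p = 1.72e-06, p = 0.0499 with an estimated correlation, and p = 0.0522 with it in the 2 kb window) and 0.095 with TBG (p = 0.00587, p = 0.0713 with an estimated correlation). The 206 regions near the 111 lowered genes had -0.332 (p = 1.1e-07, p = 0.0205 with an estimated correlation) and -0.147 (p = 0.00112, p = 0.0704 with an estimated correlation). In excitatory neuron-like nuclei the regions near the 41 raised genes had a median of 0.101 (limma camera p = 0.00018, p = 0.187 with an estimated correlation) and those near the 15 lowered genes -0.256 (p = 1.34e-05, p = 0.167 with an estimated correlation). With TBG the same regions had 0.072 (limma camera p = 0.00418, p = 0.256 with an estimated correlation) and -0.235 (p = 2.88e-05, p = 0.207 with an estimated correlation). Between the compounds the medians were 0.064 and 0.009. The raised and lowered genes were called in the RNA of the same nuclei and profiles, so these medians are no independent support for the calls. In astrocyte-like nuclei a change in the mix of clusters 3 and 12 could move RNA and accessibility together, which was not tested.

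A score of 50 genes chosen in the other sex was read in single astrocyte-like nuclei. In males its median was 0.228% of UMIs with vehicle, 0.353% with TBG and 1.09% with 5-MeO-DMT, and in females 0.171%, 0.311% and 0.828%. The share of nuclei above the 95th percentile of vehicle was 16.1% with TBG and 82.9% with 5-MeO-DMT in males, and 27.9% and 79.7% in females.

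Fkbp5 was called higher with 5-MeO-DMT in excitatory neuron-like, inhibitory neuron-like, astrocyte-like and precursor-like nuclei, and not in oligodendrocyte-like (0.80, edgeR adjusted p = 0.599), microglia-like (1.34, edgeR adjusted p = 0.996) or vascular cell-like nuclei (0.16, edgeR adjusted p = 0.92). A glucocorticoid signal that reaches all classes may underlie this, as a hypothesis. It would raise listed glucocorticoid-induced genes that no activity list holds, and their median lay above 0 in 7 of 7 classes (0.21 in excitatory neuron-like, 0.33 in inhibitory neuron-like, 0.52 in astrocyte-like, 0.06 in oligodendrocyte-like, 0.78 in precursor-like, 0.23 in microglia-like and 0.16 in vascular cell-like nuclei). In the same order 10 of 14, 7 of 11, 10 of 13, 6 of 10, 5 of 7, 5 of 8 and 9 of 11 members lay above 0, and no test was made. Fkbp5 was not taken out of these genes, so the medians are not independent of the rise that prompted the hypothesis. The classes come from the same 6 sets of nuclei. With TBG the medians were -0.02 in excitatory neuron-like, 0.07 in inhibitory neuron-like, 0.19 in astrocyte-like, -0.07 in oligodendrocyte-like, 0.09 in precursor-like, 0.04 in microglia-like and 0.22 in vascular cell-like nuclei. Fkbp5 itself changed by 0.68, 0.85, 0.82, 0.60, 0.77, 0.97 and 0.60 with TBG in the same order, called among the classes in inhibitory neuron-like nuclei only. It thus rose with TBG also where the list median lay below 0. No hormone was measured, and handling that differed between profiles stays open.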
